A study of Mus musculus with 10 samples.

How the data were processed

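RNA was measured by sequencing in 10 mouse melanomas, 5 labelled as Fes knockout (Fes KO) and 5 as wild type (Fes WT). All mice carried the Tyr::CreERT2 transgene and a conditional oncogenic Braf allele, and tumours were started by topical 4-hydroxytamoxifen at 5 mM on the back skin, per the labels' protocols. Groups and replicate numbers came from the sample titles. No label says that the tumours of a group came from separate animals, so p-values measure the spread between these tumours.

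The authors deposited a table of raw read counts per gene and a table of normalized log2 values of the same genes. FastQC, STAR version 2.51b, Subread version 1.4.6 and the builds mm10 and GRCm38 are named per the submitters' processing notes, and their settings are not given in the sources used here, nor is the strand setting of the counting. Whole numbers in the count table summed to different totals in each tumour, between 13226783 and 16599120. From the values, each deposited log2 value equals the log2 of the count divided by a size factor plus 1. The size factors recovered this way differ from median-of-ratios factors computed from the counts by at most 1.1e-11. The tables hold 47643 genes with Ensembl identifiers, of which 47224 have coordinates in the GENCODE M21 annotation (GRCm38), which was used for positions and gene classes. The mitochondrially encoded genes have 0 counts in every tumour, so that list could not be used as a sign of RNA quality.

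Counts were tested with edgeR version 4.0.16 in R version 4.3.3, with TMM normalization, genes filtered by filterByExpr with the group, a quasi-likelihood fit and 2-sided test, and Benjamini-Hochberg adjustment over the 14816 genes tested. A gene counted as changed at an adjusted p below 0.05. Log2 fold changes are Fes KO minus Fes WT with their standard errors (SE), and levels are CPM (edgeR's counts scaled to the library size) with the SD over 5 tumours. A group with 0 counts was given a floor of 3 counts over its summed library sizes. Of the 36 gene lists fixed before the data were examined, the 33 with at least 5 tested members were tested with camera from limma version 3.58.1 at a preset correlation of 0.01, 2-sided, with Benjamini-Hochberg adjustment over the lists. The hair follicle list had 3 tested members and the sex-linked list was kept as values. List levels per tumour are means of log2 CPM with a prior count of 2. Changed genes near Fes were counted within 10 Mb and compared with all other tested genes by Fisher's exact test, 2-sided. Single values were compared by exact permutation over the 252 assignments of 5 and 5 tumours, whose smallest 2-sided p is 0.00794. The best protein-coding match of each changed pseudogene was found with blastn version 2.17.0+ against the M21 transcripts.

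The rule for named genes was fixed before the data were examined. It takes Fes, its paralog Fer, its neighbours Furin and Blm, and the engineered gene Braf. Of the changed genes with a mean of at least 1 CPM in a group it takes the 10 with the largest and the 10 with the smallest log2 fold change, leaving out predicted genes and pseudogenes by symbol, which are counted. From each described list it takes up to 3 members, changed ones by p and then those with the highest mean CPM, and they are named for the lists that camera called. Members that passed over their list alone are named beside them. A further gene of the first part of the rule, and a gene that passed over its list alone, are not reported here.

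Tested on simulated counts of 14816 genes, the edgeR script recovered 47% of the genes changed 2-fold and 91% of those changed 4-fold, and 9 of its 149 calls were unchanged genes. At this depth and number of tumours, many 2-fold differences would therefore be missed. The simulated changes were placed only in genes above a minimum mean level, and genes were drawn independently of each other. Recovery of genes at low levels may thus be lower. Alternatives fixed in advance were other normalization factors, DESeq2 version 1.42.0, limma-voom with quality weights, limma on the deposited log2 values, looser and stricter filters, the replicate number as a block, 1 surrogate variable from sva version 3.50.0, covariates for Y-linked expression and for skin and muscle transcripts, other thresholds, windows and list tests, and leaving out each tumour. After seeing the data, the fits without the 3 Xist-expressing tumours and without the tumours richest in keratinocyte and muscle transcripts were added. No sample and no column was left out of the main fits. Each tumour counted as 1 replicate, as the titles number them.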

Results

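Gene expression was compared between 5 melanomas labelled as Fes knockout (Fes KO) and 5 labelled as wild type (Fes WT), all driven by activated Braf in melanocytes. Total counts ranged from 13226783 to 16599120 per tumour, and between 20505 and 22395 genes had at least 1 count. Tissue content and sex-linked expression also differed between tumours. Xist, the RNA expressed from the inactive X chromosome, was at 720, 713 and 670 CPM in Fes WT 5, Fes KO 1 and Fes KO 2, and at no more than 0.678 CPM in the other tumours, where the Y-linked gene Ddx3y was at 71.8 to 115 CPM. Keratinocyte markers had a mean log2 CPM of 7.97 in Fes KO 2 against 0.51 to 1.38 in the other Fes KO tumours, and skeletal muscle markers had 9.66 in Fes WT 3 against -0.50 to 4.93 in the other Fes WT tumours.

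The level of the targeted gene was examined as a check of the labels. Fes (ENSMUSG00000053158, chromosome 7, 80377756 to 80387946, GRCm38), which encodes a cytoplasmic tyrosine kinase, was at 38.9 ± 11.5 CPM in Fes KO and 81.3 ± 12.7 CPM in Fes WT (SD, 5 tumours each). Every Fes KO tumour, at 29.2 to 57.5 CPM, lay below every Fes WT tumour, at 72.5 to 102 CPM, with an exact 2-sided permutation p of 0.00794, the smallest this design allows. Between 473 and 879 reads per Fes KO tumour were still counted to Fes. Counts per exon were not used here, so whether these reads come from the targeted part of the gene is open, and the level shows a lower count rather than its absence. The log2 fold change of -1.06 (SE 0.19) had an adjusted p of 0.0846 over all genes in the edgeR quasi-likelihood test (Benjamini-Hochberg), which does not pass the threshold. For Fes in Fes KO against Fes WT, leaving out Fes KO replicate 4 gave -1.25 with an adjusted p of 0.0164. DESeq2 and limma-voom gave adjusted p values of 1.1e-04 and 0.0186, and over all alternatives the adjusted p ranged from 1.1e-04 to 0.244. The paralog Fer had a log2 fold change of 0.00 (SE 0.14). Furin, the gene next to Fes, had 0.35 (SE 0.11, adjusted p = 0.356) and Blm 0.30 (SE 0.22, adjusted p = 0.678). Braf, which carries the engineered allele, had 0.17 (SE 0.10, adjusted p = 0.619).

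What else differed between the Fes KO and Fes WT melanomas was asked over all genes. C7, a terminal complement component, fell from 32.0 ± 18.4 to 0.67 ± 0.29 CPM, and C1ra, a protease of the C1 complement complex, fell from 245 ± 64.2 to 74.0 ± 21.2 CPM. The matricellular protein gene Smoc2 fell from 310 ± 45.6 to 93.7 ± 44.9 CPM, and Gabra3, a subunit of the GABA-A receptor, from 63.3 ± 31.3 to 3.30 ± 1.96 CPM. Cd276, which encodes the immune checkpoint protein B7-H3, was the protein-coding gene that rose, from 53.9 ± 7.23 to 97.3 ± 16.5 CPM. In GRCm38 coordinates these are C7 (ENSMUSG00000079105) on chromosome 15 from 4988762 to 5063740, C1ra (ENSMUSG00000055172) on chromosome 6 from 124512405 to 124523443, Smoc2 (ENSMUSG00000023886) on chromosome 17 from 14279506 to 14404790, Gabra3 (ENSMUSG00000031343) on chromosome X from 72432681 to 72656848 and Cd276 (ENSMUSG00000035914) on chromosome 9 from 58524298 to 58555437.

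In total, 26 of 14816 tested genes changed in the edgeR quasi-likelihood test, 7 higher and 19 lower in Fes KO. Of these, 11 were protein-coding, 1 higher and 10 lower. At adjusted p below 0.1 there were 49 genes, and 1425 genes had an unadjusted p below 0.05. In all 26 changed genes, every tumour of the lower group lay below every tumour of the other. Over all tested genes this held for 281, or 1.90%, where chance gives 0.794% on average. Genes move together, so a single split can lie above this average, and the spread over splits was not examined. The lowest fitted value belonged to Ifi202b, a member of the interferon-inducible Ifi200 family (ENSMUSG00000026535, chromosome 1, 173962568 to 173982744), with a log2 fold change of -7.82 (SE 0.91, adjusted p = 0.00789), from 42.5 ± 9.52 to 0.175 ± 0.39 CPM. Ighg2c, an immunoglobulin heavy chain constant region, followed at -6.87 (SE 1.02, adjusted p = 0.0232). Ifi202b and Ighg2c belong to families of similar sequences, so their read counts are uncertain. In Fes KO 2, Ighg2c had 2 counts while Igkc, an immunoglobulin gene named after its value was seen, had 359. Whether loss of Fes or a strain difference between the groups of mice lowered Ifi202b and Ighg2c is open. C7 had -5.57 (SE 0.72, adjusted p = 0.0168), Gabra3 -4.25 (SE 0.65, adjusted p = 0.0411), C1ra -1.73 (SE 0.22, adjusted p = 0.0168) and Smoc2 -1.73 (SE 0.28, adjusted p = 0.0496). Ighg2c kept its call in 11 of 22 alternatives and lost it without Fes WT replicates 2 and 4 (adjusted p = 0.0568 and 0.0580) and without each Fes KO replicate (0.0542 to 0.103). Over 23 alternatives C7 and C1ra kept their calls in 16, Gabra3 in 10, and Smoc2 and Cd276 in 9. With 1 tumour left out, Gabra3 was called only without Fes WT replicate 5 (adjusted p = 0.00418), and its adjusted p was 0.0542 to 0.126 in the other such fits.

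Acp1, a low molecular weight phosphotyrosine phosphatase (ENSMUSG00000044573, chromosome 12, 30893326 to 30911589), had a log2 fold change of -1.42 (SE 0.15, adjusted p = 0.00512), and Gstt1, a glutathione transferase, -1.39 (SE 0.19, adjusted p = 0.0215). The phosphatase gene Ppef2 had -1.73 (SE 0.28, adjusted p = 0.0493) at a level of 2.42 ± 0.69 CPM in Fes WT, and the noncoding RNA RP24-185P7.1 had -1.95 (SE 0.26, adjusted p = 0.0181). Outside the rule for named genes, and named after their values were seen, Entpd2, an ectonucleotidase, had -1.20 (SE 0.17, adjusted p = 0.0232) and C1s1, the neighbour of C1ra on chromosome 6, had -0.91 (SE 0.14, adjusted p = 0.0466). Cd276 had 0.85 (SE 0.13, adjusted p = 0.0466). Over 23 alternatives Acp1 kept its call in 23, Gstt1 and RP24-185P7.1 in 15, Entpd2 in 14, C1s1 in 12 and Ppef2 in 4. Ppef2 lost its call in every fit with 1 tumour left out (adjusted p = 0.0521 to 0.182). DESeq2 called 270 genes, 92 higher and 178 lower, and limma-voom with quality weights 115, 31 higher and 84 lower. The fit with keratinocyte and muscle covariates called 113, of which 65 were higher and 48 lower. Without the 3 Xist-expressing tumours 64 were called, 36 higher and 28 lower, so in these 2 fits most called genes were higher. Leaving out 1 tumour gave 15, 11, 16 and 54 genes without Fes WT replicates 1, 2, 4 and 5, and 10, 10 and 12 without Fes KO replicates 1, 3 and 5.

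**Figure D1:**
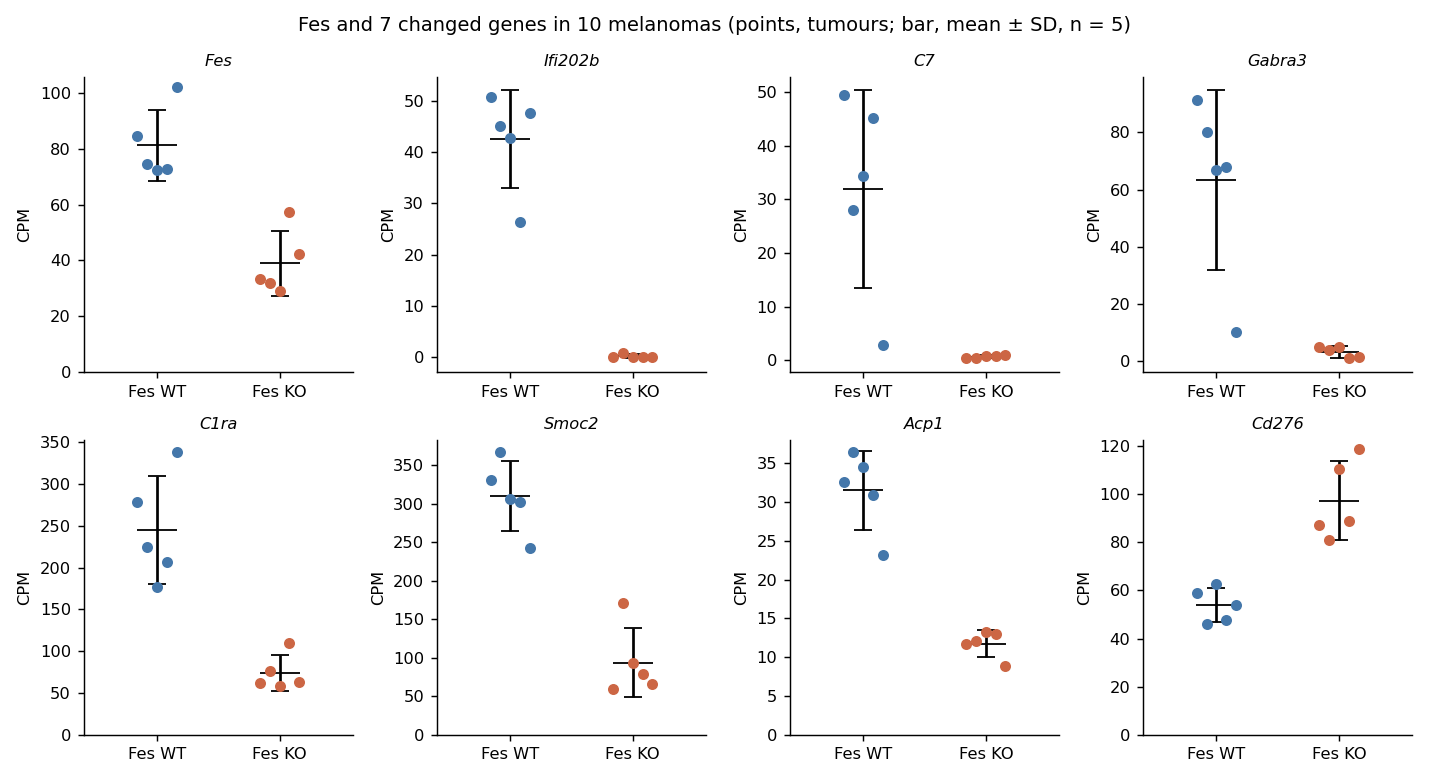
Levels of Fes and 7 changed genes, in CPM on the vertical axis, in each of the 5 Fes WT and 5 Fes KO tumours (points), with the mean and SD (bars). All Fes KO tumours lie below all Fes WT tumours for Fes (29.2 to 57.5 against 72.5 to 102 CPM) and 6 of the changed genes, and above them for Cd276.

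Pseudogenes made up 12 of the 26 changed genes, 5 higher and 7 lower in Fes KO. This is 46.2% of the changed genes against 1.57% of those tested (Fisher's exact test, 2-sided, p = 1.4e-15). Hist1h2al, which the annotation lists as a processed pseudogene on chromosome 13, had a log2 fold change of 6.06 (SE 0.65, adjusted p = 0.00212) and a mean of 1.42 CPM in Fes KO. Of the others, named after their values were seen, Rps13-ps1 on chromosome 8 had 0 counts in every Fes WT tumour and 20.99 ± 3.16 CPM in Fes KO, at least 530.1-fold higher against a floor of 3 counts over the group. Rps15a-ps8 on chromosome 4 had 7.64 (SE 0.59, adjusted p = 4.2e-04), and Gm6969 on chromosome 12 had -4.27 (SE 0.24, adjusted p = 8.4e-05). These pseudogenes share sequence with protein-coding genes, at 83.1% to 100% identity over the best aligned part, so reads can be split between them. None of the 10 tested parental genes changed in edgeR, where their lowest adjusted p was 0.209, and their log2 fold changes in the direction of the pseudogene lay between -0.59 and 0.43.

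A targeted allele can carry flanking sequence of the strain it was made in, so changed genes were counted around Fes. Within 10 Mb of Fes, 0 of 109 tested genes changed in edgeR, against 26 of 14675 elsewhere (Fisher's exact test, 2-sided, p = 1). At an unadjusted p below 0.05 there were 17 genes near Fes (15.6%) and 1406 elsewhere (9.58%), a difference in share that was not tested, DESeq2 called 4 near Fes and limma-voom 1. Among the 17 were Furin and, named after its value was seen, Klhl25, with a log2 fold change of 0.48 (SE 0.09, adjusted p = 0.103). The 26 changed genes lay on 15 chromosomes.

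Immune cell lists were tested next, because a tumour sample also holds infiltrating cells. All 17 tested macrophage markers lay below 0 in log2 fold change, with a median of -0.82, and all 26 interferon-gamma response and antigen presentation genes did, with a median of -0.72. T cell markers had a median of -1.11 with 13 of 13 below 0, and cytotoxic and NK cell markers -1.39 with 7 of 8 below 0. These levels overlapped between the groups. In macrophage markers Fes KO 2 and Fes KO 4, at a mean log2 CPM of 6.07 and 6.34, lay within the Fes WT range of 5.80 to 6.84, and Fes KO 1, Fes KO 3 and Fes KO 5 lay below it at 5.03, 4.96 and 4.97. The lysozyme gene Lyz2 was at 423 ± 202 CPM in Fes KO and 751 ± 306 CPM in Fes WT, the complement gene C1qa at 191 ± 87.0 and 325 ± 91.2 CPM, and the receptor gene Csf1r at 197 ± 78.8 and 318 ± 105 CPM. The class I genes H2-D1, B2m and H2-K1 had log2 fold changes of -1.20 (SE 0.40), -0.70 (SE 0.34) and -0.81 (SE 0.41).

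No member of these 4 lists passed over all genes in edgeR. Adjusted over the list alone, 4 cytotoxic and NK cell genes passed, named after their values were seen. They were the granzyme gene Gzmb at -2.89, Il2rb at -2.02, Eomes at -1.46 and Klrk1 at -1.34. Other examples were Ccl5 and Klrd1, each at -0.63, and from the T cell list Thy1 at -1.23, Cd4 at -0.56 and Lck at -0.82. Thy1 is also in the fibroblast list. It was at 609 CPM in Fes WT, against 4.37 for Cd4 and 3.01 for Lck, so it cannot be read as a T cell signal here. With camera, these lists shifted lower, with adjusted p = 6.6e-10 for macrophage markers, 2.1e-09 for the interferon-gamma list, and 2.0e-05 for each of the T cell and the cytotoxic and NK lists. None of the calls held with an estimated correlation, where the adjusted p values were 0.454 for macrophage, 0.667 for interferon-gamma, 0.667 for T cell and 0.454 for cytotoxic and NK markers.

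Of the other immune lists, 4 were called lower by camera. Neutrophil markers had a median log2 fold change of -1.09 (adjusted p = 0.00459, and adjusted p = 0.684 with an estimated correlation), with Csf3r at -1.15 but Retnlg at 0.52 and Mmp9 at 0.35. Type I interferon response genes had -0.42 (adjusted p = 0.0156, and 0.738 with an estimated correlation), with Ifit2 at -0.08, Bst2 at -0.30 and Ifit3 at -0.17. Mast cell markers had -0.30 (adjusted p = 0.0272, and 0.684 with an estimated correlation), with Tpsb2 at -0.15, Mcpt4 at -0.33 and Cpa3 at -0.24. Dendritic cell markers had -0.09 (adjusted p = 0.0345, and 0.667 with an estimated correlation), with Clec10a at -0.97, Fscn1 at 0.32 and Zbtb46 at 0.00. Without Fes WT replicate 5 none of these 4 calls remained, with medians of -0.19, 0.07, -0.23 and -0.15 and adjusted p values of 0.179, 0.757, 0.149 and 0.0576 in that order. The type I interferon median thus changed sign, and the dendritic cell median moved further from 0. For the list type I interferon response the call was also lost without Fes KO replicates 3 and 5 (adjusted p = 0.0854 and 0.238). For the list mast cell markers it was lost without Fes WT replicate 2 (0.158) and Fes KO replicates 1, 4 and 5 (0.0663, 0.128 and 0.185). For the list dendritic cell markers it was lost without Fes WT replicates 2 and 3 (0.0735 and 0.251) and Fes KO replicates 1, 3 and 5 (0.0663, 0.0854 and 0.0544). B and plasma cell markers were not called (adjusted p = 0.295), and their median of 0.01 and mean of -0.44 differed in sign.

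**Figure D2:**
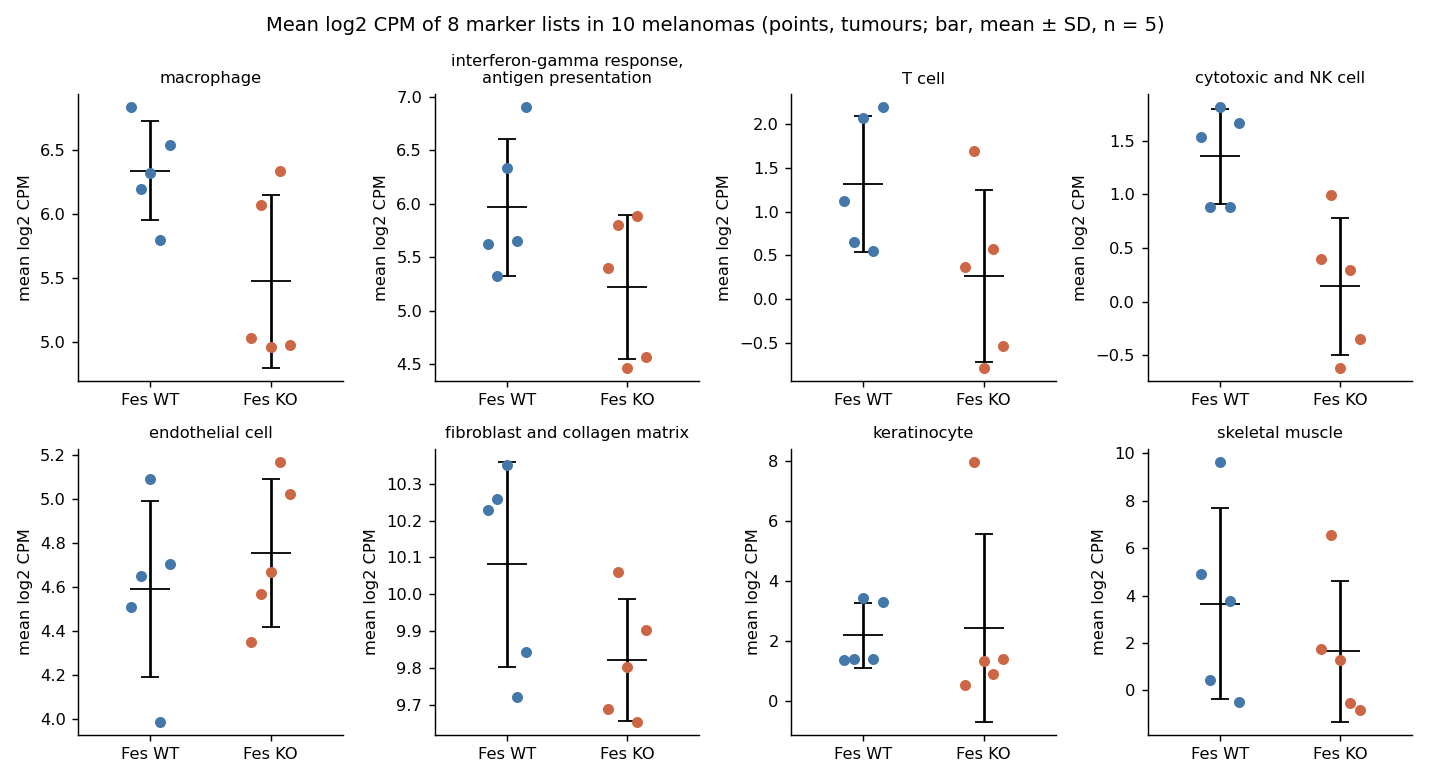
Mean log2 CPM of 8 marker lists on the vertical axis in each of the 5 Fes WT and 5 Fes KO tumours (points), with the mean and SD (bars). Macrophage markers average 6.34 in Fes WT and 5.47 in Fes KO, endothelial markers 4.59 and 4.76, and the keratinocyte panel shows Fes KO 2 at 7.97.

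Proliferation and melanocyte lists were measured in bulk tumour RNA, which does not assign them to tumour cells. Of the proliferation genes, 28 of 28 lay above 0, with a median log2 fold change of 0.44 (camera adjusted p = 2.3e-05, and 0.684 with an estimated correlation). Mki67 was at 95.7 ± 49.9 CPM in Fes KO and 68.5 ± 47.7 CPM in Fes WT, Top2a at 93.8 ± 51.2 and 69.0 ± 47.9 CPM, and Pcna had a log2 fold change of 0.28 (SE 0.18). Without the 3 Xist-expressing tumours the median was -0.11, so the direction turned. Melanocyte differentiation and pigmentation genes had a median of 0.83 with 16 of 18 above 0 (adjusted p = 0.00139, and 0.684 with an estimated correlation). The pigment enzyme gene Dct was at 326 CPM in the keratinocyte-rich Fes KO 2 and at 1.90 to 47.0 CPM in the other Fes KO tumours, while Sox10 had 0.22 (SE 0.25) and Cdk2 0.29 (SE 0.08). Without Fes KO replicate 2 the list's median was 0.18 with an adjusted p of 0.173.

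Undifferentiated and neural crest genes had a median of 0.24 with 15 of 20 above 0 (adjusted p = 0.00607, and 0.454 with an estimated correlation), with Aqp1 at 1.29 (SE 0.88), Tgfbi at 0.88 (SE 0.44) and Nes at 0.99 (SE 0.42). Immediate early genes had -0.52 with 16 of 16 below 0 (adjusted p = 9.3e-04, and 0.684 with an estimated correlation), with Egr1 at -0.50 (SE 0.80), Nr4a1 at -0.23 (SE 0.58) and Klf6 at -0.35 (SE 0.20). Their call was lost without Fes WT replicate 1, at a median of -0.13 and an adjusted p of 0.182. Skeletal muscle markers had -2.96 with 18 of 18 below 0 (adjusted p = 0.00205, and 0.723 with an estimated correlation), with Acta1 at -2.99 (SE 2.39), Myh4 at -3.53 (SE 2.72) and Atp2a1 at -2.81 (SE 2.35). Without the muscle-rich Fes WT replicate 3 that median was 0.83 with an adjusted p of 0.675.

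Calls close to the threshold were made for 4 further lists, and each was kept in 10 to 14 of 26 alternative settings. Senescence and secreted inflammatory factors had a median of -0.47 (adjusted p = 0.0439, and 0.684 with an estimated correlation), with the stromelysin gene Mmp3 at -4.81 (SE 1.45) and Igfbp5 at -0.55 (SE 0.60) but Igfbp3 at 0.50 (SE 0.40). Notch targets had 0.19 (adjusted p = 0.0476, and 0.454 with an estimated correlation), with Heyl at 0.18, Jag1 at 0.07 and Notch3 at -0.10. Every Fes KO tumour had a higher mean of the Notch list, 4.49 to 4.90 log2 CPM, than every Fes WT tumour, 4.08 to 4.44. Exact permutation of these means gave p = 0.00794, the smallest possible, and an adjusted p of 0.262. The sterol and fatty acid synthesis list had 0.13 (adjusted p = 0.0476, and 0.738 with an estimated correlation), with Scd1 at 0.30, Srebf1 at -0.23 and Fasn at 0.04. The p53 target list had 0.12 (adjusted p = 0.0476, and 0.684 with an estimated correlation), with Phlda3 at 0.55, Plk2 at 0.69 and Cdkn1a at 0.51. Single tumours ended these calls. The list senescence and secreted inflammatory factors was not called without Fes WT replicates 2 and 5 (adjusted p = 0.104 and 0.410) or Fes KO replicates 1, 2 and 3 (0.0616, 0.173 and 0.215). The list Notch targets was not called without Fes WT replicates 2, 3 and 5 (0.123, 0.0541 and 0.0995) or Fes KO replicates 1, 2 and 5 (0.0690, 0.0602 and 0.114). The list sterol and fatty acid synthesis was not called without Fes WT replicates 1, 2, 3 and 4 (0.189, 0.166, 0.251 and 0.273) or Fes KO replicates 2, 3 and 4 (0.230, 0.0854 and 0.0571). The list p53 targets was not called without Fes WT replicates 1, 2 and 5 (0.0545, 0.0735 and 0.436) or Fes KO replicates 1, 2 and 5 (0.106, 0.179 and 0.212).

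Adjusted over the list alone, 2 genes of the FoxO and PI3K feedback list were lower, Bcl6 at -0.66 (SE 0.15) and Txnip at -1.03 (SE 0.29), and neither passed over all genes in edgeR (adjusted p = 0.193 and 0.313).

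In all, camera called 17 of 33 lists, 11 lower and 6 higher, and with an estimated correlation, with fry and with exact permutation of list means it called 0, with 3 lists at an unadjusted p below 0.05 by the estimated correlation. The permutation could hardly call a list, since Notch targets, at its smallest possible p of 0.00794, had an adjusted p of 0.262. Single tumours moved the camera count to 11 without Fes WT replicate 2 and 10 without Fes WT replicate 5. The remaining lists were not called. MAPK output genes had a median of 0.14 (adjusted p = 0.149), and Wnt/beta-catenin targets 0.14 (adjusted p = 0.452). Endothelial markers had a median of 0.11 (adjusted p = 0.202), fibroblast and collagen matrix genes -0.24 (adjusted p = 0.236), and erythrocyte markers -0.40 (adjusted p = 0.246). The 6 tested keratinocyte markers had a median of 2.93 (adjusted p = 0.300), which reflects the level in Fes KO 2. Hypoxia and glycolysis genes had -0.13 (adjusted p = 0.329), adipocyte markers -0.08 (adjusted p = 0.400), the TGF-beta and mesenchymal program -0.03 (adjusted p = 0.440) and ribosome biogenesis and Myc genes 0.08 (adjusted p = 0.452). FoxO and PI3K feedback genes had a median of -0.05 (adjusted p = 0.459) and oxidative phosphorylation genes -0.02 (adjusted p = 0.879). In Schwann cell, unfolded protein and YAP/TAZ lists the median and the mean differed in sign, with medians of -0.22, -0.11 and 0.06 and adjusted p values of 0.531, 0.786 and 0.962.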

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

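The splits of the tumours for changed genes, lists and genes near Fes and the covariate tests were planned before their values were seen. All other tests here were chosen only after the result was seen, as was the grouping of C7, C1ra, C1s1 and Smoc2.

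Single tumours lay far from the other 4 of their group in 17 of 240 groups of 5 values, where 12 would be expected, since chance flags about 1 in 20 groups. Values are log2 CPM, with the nearest other tumour in brackets. Among genes, Ifi202b was at 4.72 in Fes WT 4 (5.42), and at 0.0056 in Fes KO 2, where the other Fes KO tumours had 0 counts. Ighg2c was at -1.97 in Fes KO 2 and Hist1h2al at -2.36 in Fes WT 2, in each case the only tumour of its group with counts. C7 was at 1.52 in Fes WT 5 (4.82) and Gabra3 at 3.37 in Fes WT 5 (6.07), so both changed genes were also low in 1 Fes WT tumour. Egr1 was at 9.996 in Fes WT 1 (6.86) and Heyl at 8.09 in Fes KO 5 (7.88). Fasn was lowest in Fes KO 4 at 7.40 (7.87) and Zbtb46 in Fes WT 5 at 4.20 (5.02).

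Among list means, Fes KO 2 was highest for keratinocyte markers at 7.97 (1.38), adipocyte markers at 5.63 (2.95) and oxidative phosphorylation at 6.71 (6.48), and lowest for Schwann cell markers at 6.06 (6.96). Sterol and fatty acid synthesis was highest in Fes WT 5 at 6.44 (5.03), erythrocyte markers in Fes KO 4 at 4.18 (1.81), and the TGF-beta and mesenchymal program was lowest in Fes WT 4 at 6.11 (6.31).

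For the 26 changed genes, 2 of 100 splits gave as many, the real one included, so a count of this size was rare among splits. The highest other split called 108 genes, which points to a structure of the samples, so the count alone excludes neither this nor chance. That split exchanged Fes WT 5 and Fes KO 2, shared 0 genes with the 26, and shifted skeletal muscle markers by a median of -6.99. For the 17 shifted lists chance was not excluded, as 19 of 100 splits gave as many and the highest other gave 22. For the 0 changed genes near Fes in edgeR all 100 of 100 splits were as large, the highest other giving 3, so this count cannot separate the groups from chance.

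The first pattern is 11 genes whose groups lay at least 4-fold apart, Ifi202b, Gm26862 and 9 pseudogenes. Over all possible splits only 1, the real one, gave as many, and the highest other gave 1. A random split of the tumours is thus an unlikely source. The 4-fold gap was chosen after these genes were seen, so the count alone does not exclude chance. A change of the parental genes carried over by shared reads was argued against, since 10 tested parents moved by a median of -0.048 in the pseudogenes' direction. Sequence carried along with the Fes allele was argued against as the whole source, since 1 of the 26 changed genes lay within 20 Mb of Fes. That gene was Gm26862, itself 1 of the 11, so for it this source is not argued against. A background strain difference between the 2 groups of mice may give genes spread over 9 chromosomes, but loss of Fes could too, so these cannot be told apart without the breeding history.

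The second pattern is the lower immune lists, 8 called with a preset correlation and none with an estimated one (adjusted p from 0.454 to 0.738), with mean scores of 3.45 and 3.41 in Fes KO 2 and Fes KO 4, inside the Fes WT range of 3.08 to 4.29, and of 2.60, 2.04 and 2.08 in Fes KO 1, Fes KO 3 and Fes KO 5. Without the tumour Fes WT 5 the medians were -0.72, -0.48, -0.90 and -1.15 for the macrophage, interferon-gamma, T cell and cytotoxic lists, which were still called, and -0.19, 0.07, -0.23 and -0.15 for the neutrophil, type I interferon, mast cell and dendritic cell lists, which were not. With 4 of 8 still called, at the bound of the test, 1 inflamed Fes WT tumour is neither excluded nor shown as the source. A higher share of tumour cells in Fes KO would lower endothelial and fibroblast markers alike. The score changes were -0.84 for the 8 immune lists and -0.05 for the mean of the endothelial and fibroblast lists, with an exact permutation p of 0.0794 for the difference. That -0.05 joins opposite changes, -0.26 for the fibroblast list and 0.17 for the endothelial list. A higher share of tumour cells thus cannot be told apart from fewer or less active immune cells at this number of tumours. The test was first run on the 4 lists with the smallest p, where the difference was -0.92 with an exact permutation p of 0.0317.

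The third pattern is lower C7, C1ra, C1s1 and Smoc2. With the fibroblast list score as a covariate their median log2 fold change was -1.68, and with the interferon-gamma list score -1.59, against -1.73 without, so neither score is likely to account for them alone. The fibroblast score itself differed by -0.26 (Fes KO minus Fes WT), and fibroblast content that this list does not track was not tested. With the fibroblast score C7 had -5.42 (SE 0.79) against -5.57 (SE 0.72), C1ra -1.88 (SE 0.25) against -1.73 (SE 0.22), C1s1 -0.997 (SE 0.17) against -0.91 (SE 0.14) and Smoc2 -1.49 (SE 0.26) against -1.73 (SE 0.28), and the calls of C7, C1s1 and Smoc2 ended with the extra coefficient (adjusted p = 0.0593, 0.0837 and 0.0886). With the interferon-gamma score C1s1 had -1.02 (SE 0.16) and Smoc2 -1.68 (SE 0.32), and their calls ended (adjusted p = 0.0558 and 0.151), while C7 had -6.27 (SE 0.72) and C1ra -1.49 (SE 0.22) with adjusted p of 0.0188 and 0.0432. A difference between the mice other than Fes, and loss of Fes itself, stay open.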

How the results depend on the processing

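The fits without the 3 Xist-expressing tumours and without the skin-rich and the muscle-rich tumour were chosen after seeing the data; the other alternatives were planned. Over 23 alternatives Acp1, Gm6969, Gm10039 and Rps15a-ps8 kept their calls in 23, Ifi202b, Rps13-ps1, Gm13736 and Gm15920 in 22, C7 and C1ra in 16, Gabra3 in 10, Cd276 and Smoc2 in 9 and Ppef2 in 4. For lists, 674 values kept direction and side of the threshold, 123 fell below it, 21 passed it and 40 reversed. For named genes these were 1714, 181, 8 and 70, and a gene without an adjusted p counted as not called. Hist1h2al and Ighg2c were removed by the stricter filter, which gave no value for them. On simulated counts, with changes placed only in genes above a minimum mean level, 47% of 2-fold and 91% of 4-fold changes were recovered, so smaller differences would often be missed. For the changes below the cause was not tested, except that leaving out tumours leaves fewer samples and a looser threshold passes more genes.

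For genes changed in Fes KO against Fes WT, the 26 became 270 with DESeq2 (26 shared), 115 with limma-voom (24 shared), 42 with 1 surrogate variable (24 shared), 113 with keratinocyte and muscle covariates (25 shared), 64 without the 3 Xist-expressing tumours (15 shared) and 49 at adjusted p below 0.1. With the replicate number as a replicate block the count was 4, all among the 26, though the numbers do not pair the tumours. Leaving out 1 tumour gave 10 to 54, with 15, 11, 16 and 54 without Fes WT replicates 1, 2, 4 and 5, and 10, 10 and 12 without Fes KO replicates 1, 3 and 5. For Fes in Fes KO against Fes WT, calls were gained with DESeq2 (-1.07), limma-voom (-1.16), keratinocyte and muscle covariates (-1.19) and without Fes KO replicate 4 (-1.25), and leaving out 1 tumour gave -1.25 to -0.97. For gene lists shifted in Fes KO against Fes WT, the 17 became 0 with an estimated correlation, 0 with fry and 0 with exact permutation of list means, where 3, 4 and 3 lists had an unadjusted p below 0.05, and 10 to 20 when 1 tumour was left out, with 11 without Fes WT replicate 2 and 10 without Fes WT replicate 5. The permutation could hardly call a list, as its smallest p of 0.00794 became 0.262 after adjustment. For changed genes near Fes, the 0 in edgeR (17 at an unadjusted p below 0.05) became 4 with DESeq2, and 1 each with limma-voom, keratinocyte and muscle covariates, without the 3 Xist-expressing tumours, within 20 Mb and without Fes WT replicate 5 (range 0 to 1).

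The reversals below are log2 fold changes that changed sign, for genes, and turned directions of the list test, for lists, each given with its median. In the reversals of this paragraph, the median itself kept its sign for YAP/TAZ targets except with keratinocyte and muscle covariates, for keratinocyte markers with the Y-linked covariate and with keratinocyte and muscle covariates, and for the skeletal muscle, Schwann cell, hypoxia and unfolded protein lists. With 1 tumour left out, the YAP/TAZ median also changed sign, and the skeletal muscle median did so without Fes WT replicate 3. Fer was near 0, at -0.0039 with RLE factors and DESeq2, -0.0014 with upper-quartile factors, -0.0017 on the deposited values, -0.0066 without a filter and -0.0010 with a stricter filter. Zbtb46, also near 0, had -0.0041 with RLE factors, -0.0058 with upper-quartile factors, -0.0046 with DESeq2, -0.0068 without a filter, -0.0017 with a stricter filter and -0.0043 with 1 surrogate variable. Without the 3 Xist-expressing tumours Fer had -0.12, Srebf1 0.057, Mki67 -0.16, Top2a -0.17, Cd4 0.22, Ifit2 0.092, Bst2 0.14, Nr4a1 0.039, Ifit3 0.64, Fasn -7.9e-04, Zbtb46 -0.058 and Jag1 -0.33, and list proliferation had -0.11, list p53 targets -0.056, list keratinocyte markers -0.73, list hypoxia and glycolysis -0.14, list YAP/TAZ targets 0.20 and list ribosome biogenesis and Myc -0.084. With keratinocyte and muscle covariates Acta1 had 0.48, Myh4 1.39, Atp2a1 0.83, Egr1 0.33, Mmp9 -0.0054, Notch3 0.050, list sterol and fatty acid synthesis -0.036, list keratinocyte markers 0.0016, list skeletal muscle markers -0.037, list oxidative phosphorylation 0.024 and list YAP/TAZ targets -0.091. The replicate block gave 0.044 for Egr1 and -0.16 for keratinocyte markers. The Y-linked covariate gave -0.024 for Jag1, -0.012 for Fasn, 0.22 for keratinocyte markers and 0.088 for YAP/TAZ targets. Without the skin-rich and the muscle-rich tumour Fer had -0.023, Jag1 -0.072, keratinocyte markers -1.02, oxidative phosphorylation 0.035 and YAP/TAZ targets 0.077. Limma-voom gave -0.18 for keratinocyte markers, 0.031 for oxidative phosphorylation and 0.13 for YAP/TAZ targets, which had 0.055 on the deposited values. With 1 surrogate variable list adipocyte markers had 0.15, list Schwann cell and nerve markers -0.35 and oxidative phosphorylation 0.045, and by permutation of means list unfolded protein and amino acid stress, at a median of -0.11, had a mean that went the other way.

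With 1 tumour left out, ranges that include a reversal were -7.43 to 1.10 for Acta1, -9.74 to 2.86 for Myh4, -7.70 to 2.36 for Atp2a1, -0.96 to 0.34 for Ifit3, -0.16 to 0.84 for Mmp9, -0.029 to 0.13 for Fasn, -0.14 to 0.074 for Zbtb46, -0.22 to 0.088 for Notch3, -1.14 to 0.94 for Egr1, -1.08 to 0.044 for Nr4a1, -0.81 to 0.091 for Bst2, -1.08 to 0.065 for Cd4, -0.071 to 0.073 for Fer, -0.026 to 0.32 for Heyl, -0.27 to 0.027 for Ifit2, -0.080 to 0.25 for Jag1, -0.0024 to 0.75 for Retnlg and -0.56 to 0.024 for Tpsb2. For lists, where the test direction turned in at least 1 such fit, they were -0.086 to 0.14 for list YAP/TAZ targets, -1.83 to 0.85 for list adipocyte markers, -1.77 to 3.93 for list keratinocyte markers, -0.098 to 0.098 for list oxidative phosphorylation, -0.014 to 0.16 for list ribosome biogenesis and Myc and -0.18 to -0.032 for list unfolded protein and amino acid stress.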

Other observations

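No further test was added for the values below, which were chosen after they were seen. Cells of the skin and the tissue under it varied more between single tumours than between the groups. Skeletal muscle markers had a mean log2 CPM of 9.66 in Fes WT 3, 6.56 in Fes KO 2, 4.93 in Fes WT 1 and 3.79 in Fes WT 4, and at most 1.76 in the others. Adipocyte markers were highest in Fes KO 2 at 5.63 and Fes WT 3 at 5.55, so muscle and fat transcripts were high in the same 2 tumours. Melanocyte differentiation genes were at 5.17 in Fes KO 2, which also had the highest keratinocyte level, and at 3.18 in Fes WT 3. Neutrophil markers were highest in Fes WT 5 at 4.02 and Fes KO 4 at 3.46.

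Proliferation genes were highest in Fes KO 2 at 5.64 and Fes WT 3 at 5.31, and lowest in Fes WT 5 at 3.51. The hair follicle gene Tchh was at 5924 CPM in Fes KO 2 and 326 CPM in Fes WT 3, and at most 2.03 CPM in the other tumours. Whether hair follicles contributed to the proliferation and melanocyte levels was not tested. The 3 leading principal components held 31.7%, 21.2% and 16.5% of the variance.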
